A study of Mus musculus with 7 samples.

How the data were processed

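Lung cells of 7 mice, 3 Smad4fl/fl and 4 Smad4iko, were measured by 10x Genomics 3' single-cell RNA sequencing, with 1 library per mouse and 150 bp paired-end reads per the labels' protocols. Tissue was digested with collagenase and DNase, strained and freed of red cells before loading, per the same protocols. For each library the authors deposited a sparse matrix of counts, whole numbers of UMIs per gene and barcode, with no normalization. Per the file headers these matrices were written by Cell Ranger 6.1.1. The submitters' processing notes name fastp and UMI-tools, without versions, and the build mm10, without saying which step each belonged to. The values show that each barcode held at least 500 UMIs. The features named 31253 gene IDs, of which 31184 matched the GENCODE M21 annotation of the same build, and coordinates come from that annotation.

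The libraries held 66557262, 46449235 and 58270642 UMIs in Smad4fl/fl 1 to 3 and 58092498, 47279946, 54790862 and 52193570 UMIs in Smad4iko 1 to 4. Cells were kept with at least 300 genes, at least 600 UMIs and at most 20% of UMIs from mitochondrially encoded genes, which left 50955 of 55671 barcodes. Scrublet, as built into scanpy 1.11.5 and run per library with an expected rate of 6%, marked 1284 of these as doublets (2.52%; 1.75% to 3.79% per library), and they were removed. Libraries within a group were checked for duplicates by a chi-square of their summed counts, which was 77.5 to 601 per gene, so none was a copy of another. The labels give each library as a separate mouse sample.

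Cells of the 7 libraries were clustered together without batch integration. Log-normalised counts of 2000 variable genes, chosen without sex-linked, immunoglobulin and mitochondrial genes and without Smad4, were reduced to 40 principal components. A graph of 15 neighbours was clustered with leidenalg 0.10.2 at resolution 1, which gave 47 clusters, and 4 mixed clusters, picked after their leading genes were seen, were split at resolution 0.5. Clusters were named from 34 marker sets. A class can hold several clusters, and clusters of T cells were led by genes such as Trac, Cd3d and Cd8b1, NK cells by Gzma, Ncr1 and Klrb1c, gCap by Gpihbp1, Plvap and Sema3c, aCap by Ednrb, Fibin and Apln, and alveolar macrophages by Ear1, Chil3 and Mrc1. Others were neutrophils (S100a8, Cxcr2, Csf3r), B cells (Cd79a, Ms4a1, Ebf1), non-classical monocytes (Cd300e, Treml4, Cx3cr1), interstitial macrophages (C1qa, C1qc), cDC1 (Xcr1, Itgae) and cDC2 (Cd209a, Mgl2). A T cluster of 103 cells was led by the interferon-stimulated genes Ifit1 and Ifit3, and an alveolar macrophage cluster by cell cycle genes such as Top2a. Clusters whose leading genes went against a name, or that rested on too few markers or UMIs, stayed unnamed, 2386 cells or 4.80% of those kept. Class names rest on these rebuilt clusters and not on an annotation by the authors.

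UMI counts were summed per library and class, so that the mouse is the replicate and not the cell. A class was tested when every library held at least 30 of its cells, which gave 11 classes, and 5 more classes with at least 15 cells in every library were added after seeing the data. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (filterByExpr, TMM, genotype as the only term), with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. Smad4 was also adjusted over the 11 classes. CPM are UMIs scaled to the total UMIs of the class in the library. Where a group held 0 UMIs, a fold change was computed against a floor of 3 counts over the group. Such floors and all confidence statements on counts cover counting error only. DESeq2 1.42.0 (Wald test, own size factors) served as the other tool. It took all genes with at least 1 UMI and its own filter on low means, 184923 tests against 90592 with edgeR, so its counts differ from those of edgeR by the genes entered as well as by the test. Numbers of cells per class were tested with edgeR against the kept cells of the library, with a two-sided exact permutation test over the 35 splits of 7 libraries beside it, whose smallest p is 0.0286. Differences of the genotype effect between classes were tested with limma 3.58.1 on the difference of log2 CPM (prior count 2) within each library. Of 30 gene lists, those with at least 5 tested members in a class were tested with camera at a preset correlation of 0.01, adjusted over all lists and classes, and again with an estimated correlation.

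The cell filters, the tests, the marker sets, the gene lists, the alternatives listed next and the rule for naming genes were fixed before the data were examined. The rule names Smad4 in every tested class. In the 3 classes with the most calls it takes up to 12 genes in each direction, and elsewhere up to 5. These must pass the threshold with an average log2 CPM of at least 5 and no overlap between the groups, and their level must be at least 10% of that in the highest class. Sex-linked and predicted genes and immunoglobulin or T cell receptor segments are left out. Of each list described, up to 4 members with the smallest p are named. The 6 lists described were picked after their tests were seen.

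The gene, list and share tests were tested on simulated counts with the means and library sizes of the real samples and 200 changed genes, with genes drawn independently of each other, on Python 3.11.15 and R 4.3.3. These alternatives were DESeq2, median-of-ratios size factors, no low-count filter, the replicate number as a block, doublets kept, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), the sex read from expression as a covariate, equal cells per library, genes at the level of free RNA left out, an estimated correlation for lists, shares within the compartment, TMM factors for shares, another prior count (0.5), and each library left out in turn. Added after seeing the data were a covariate for Smad4iko 3 and 4 (for lists also with an estimated correlation), Smad4iko 1 and 2 alone, and genes within 25 Mb of Rosa26 left out. Free RNA was not subtracted from the counts. Trajectories, cell communication and splicing were not analysed here.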

Results

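The study compared the lungs of mice in which Smad4 can be deleted by tamoxifen with those of floxed littermates that lack Cre. SMAD4 is the common mediator that carries signals of the TGF-beta and BMP families into the nucleus. Smad4iko mice carried floxed Smad4 alleles and creERT2, a Cre recombinase that tamoxifen activates, at the Rosa26 locus, which is expressed in nearly all cells. Both genotypes received 5 intraperitoneal injections of tamoxifen at 75 mg/kg between postnatal days 21 and 26, and peripheral lung was collected at 8 weeks of age. Single cells of 3 Smad4fl/fl and 4 Smad4iko mice were profiled by droplet-based 3' RNA sequencing, 1 library per mouse. The libraries held 46449235 to 66557262 unique molecular identifiers (UMIs) in 55671 barcodes. After filtering and removal of predicted doublets 49671 cells remained, from 6378 to 8142 per library, with a median of 4463 to 6324 UMIs per cell. The labels do not give the sex of the mice. By Xist and the Y-linked gene Ddx3y, Smad4fl/fl 3 and Smad4iko 3 were female and the other libraries male. Cells were assigned to 32 classes by marker genes, and each class name below stands for cells like that type by its markers.

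The lung cells were mostly leukocytes. T cells made up 25.4% ± 8.06 (SD, n = 3) of Smad4fl/fl and 25.0% ± 4.60 (SD, n = 4) of Smad4iko cells, alveolar macrophages 12.9% ± 3.73 and 12.5% ± 2.99, and neutrophils 9.42% ± 5.40 and 19.1% ± 8.39. Smad4fl/fl 1 held far more stroma than the other libraries, with 18.5% endothelial and 17.6% mesenchymal cells against 1.57% to 5.31% and 0.663% to 4.28% elsewhere. It also held 15.3% of cells that no marker set named, against 1.81% to 3.95%. A second difference between libraries ran within the Smad4iko group. Of the T cells of Smad4iko 3 and 4, 77.5% and 69.2% fell into 1 cluster that held 1.17% to 2.78% of the T cells of the other 5 libraries. Such a cluster also existed for B cells, NK cells, neutrophils and alveolar macrophages. Over these 5 classes it held 69.2% to 98.3% of the cells of Smad4iko 3 and 4 and 0.301% to 7.88% of the cells of the others. On the first principal component of the expression of each class, which took 30.7% to 47.7% of the variance, both libraries lay beyond the other 5 in all 11 classes tested. Values with Smad4iko 3 and 4 marked by a covariate are therefore given below for results described here whose call they change. Most genes called only with it are given as counts. These libraries are of 1 genotype only, so no comparison of genotypes within them can be made. With the covariate the genotype effect therefore rests on Smad4iko 1 and 2 against the controls, and Smad4iko 3 and 4 add only to the estimate of spread.

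**Figure D1:**
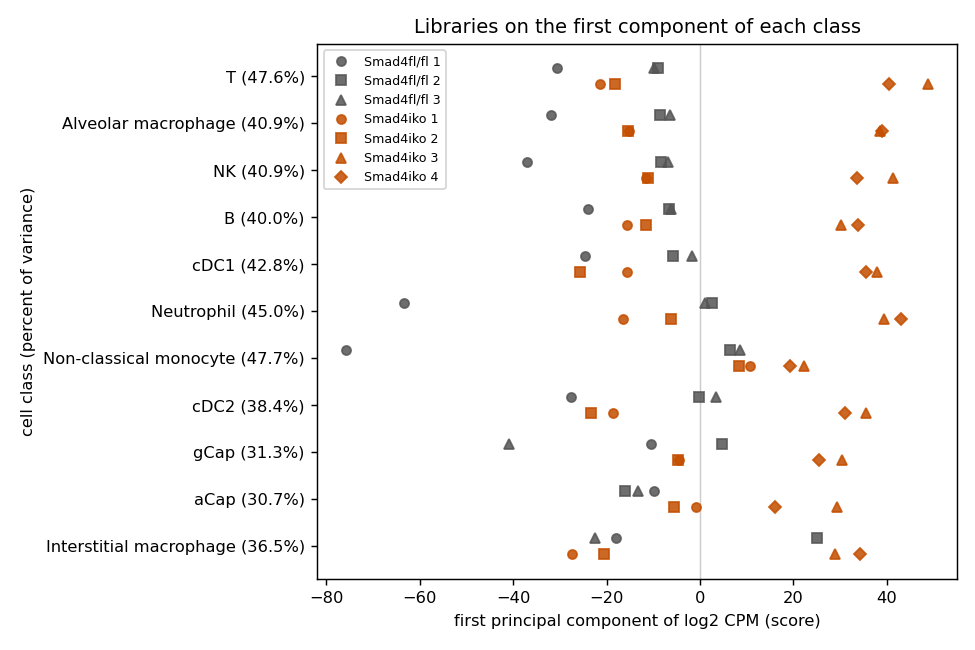
Score of each library on the first principal component of log2 CPM (x axis) in each of the 11 tested classes (y axis, with the percent of variance the component took); grey symbols are the 3 Smad4fl/fl and orange symbols the 4 Smad4iko libraries, and the symbol shape gives the replicate. Smad4iko 3 and 4 lie beyond the other 5 libraries in all 11 classes.

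The first question was how far Smad4 itself was reduced in each class. Smad4 (ENSMUSG00000024515, chromosome 18, 73639009 to 73703780, minus strand, mm10) was lower on average in Smad4iko in all 11 classes tested. It fell in T cells, from 133 ± 2.41 CPM (SD, n = 3) to 78.8 ± 15.01 CPM (SD, n = 4), a log2 change of -0.65 ± 0.13 (SE). All 4 Smad4iko libraries lay below all 3 Smad4fl/fl libraries in T cells, in B cells, in cDC1 (cross-presenting dendritic cells), in general capillary endothelium (gCap) and in alveolar macrophages. In B cells it was 66.0 ± 4.42 against 45.5 ± 7.75 CPM, in cDC1 58.6 ± 17.2 against 36.4 ± 9.07 CPM, and in gCap 105 ± 18.2 against 79.3 ± 4.01 CPM. In neutrophils it was 48.5 ± 16.3 against 43.98 ± 7.35 CPM, a log2 difference of -0.03 ± 0.28 (0.08 with the covariate for Smad4iko 3 and 4). The edgeR quasi-likelihood test gave an adjusted p of 0.00580 for T cells when Smad4 was adjusted over the 11 classes, 0.0503 each for B cells, cDC1 and gCap, 0.105 for alveolar macrophages and 0.913 for neutrophils. Adjusted over all genes of the class, no class passed with edgeR (0.729 in T cells), and T cells passed with DESeq2 (0.0201). The labels do not name the deleted exon, and 3' tags can come from transcripts that lack an internal exon, so these levels are no measure of recombination. Without Smad4fl/fl 2 the log2 difference was 0.02 in interstitial macrophages and 0.01 in non-classical monocytes, against -0.41 and -0.29 with it.

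The next comparison asked whether the genotypes differed in the makeup of the lung. Platelets were more frequent in Smad4iko on average, at 0.367% ± 0.124 (SD, n = 4) against 0.0808% ± 0.0294 (SD, n = 3) of cells, and erythroid cells stood at 0.443% ± 0.392 against 0.0467% ± 0.0238. In both classes all 4 Smad4iko libraries lay above all 3 Smad4fl/fl libraries. Gamma-delta T cells, which in the lung include producers of IL-17, were 2.19% ± 1.03 against 0.594% ± 0.564, and neutrophils were above all Smad4fl/fl libraries in 3 of 4 Smad4iko libraries. Alveolar fibroblasts were 3.61% ± 5.74 against 0.282% ± 0.331, where 10.2% came from Smad4fl/fl 1 and 0.326% and 0.274% from the others. No class passed the correction: of 32 classes edgeR called 0, with 3 at an unadjusted p under 0.05 (platelets, erythroid cells and gamma-delta T cells; adjusted p 0.130, 0.169 and 0.403). The log2 differences of these 3 were 2.15 ± 0.54, 3.22 ± 0.98 and 1.88 ± 0.76 (SE). Erythroid cells were 0.897% and 0.646% in Smad4iko 3 and 4 against 0.110% and 0.121% in 1 and 2, and with the covariate for these libraries their log2 difference was 1.29 (adjusted p = 0.651). On simulated numbers of cells the test recovered 36.7% of classes changed 8-fold, and 3 of its 25 calls were false. The changed classes were drawn from larger classes only. Platelets (119 cells over all libraries) and erythroid cells (141) could not be among them, so this rate does not describe them. A two-sided exact permutation test of platelet shares gave p = 0.0286, the smallest that 3 against 4 libraries allow. The protocol lysed red cells before loading, which can set the erythroid share. NK cells (11.9% ± 8.34 and 8.00% ± 3.34) and B cells (8.14% ± 4.99 and 9.87% ± 4.69) overlapped between the groups. The difference in gCap, 6.40% ± 7.09 against 2.51% ± 0.741, rested on Smad4fl/fl 1: the log2 difference was -1.35 with it and 0.04 without it.

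**Figure D2:**
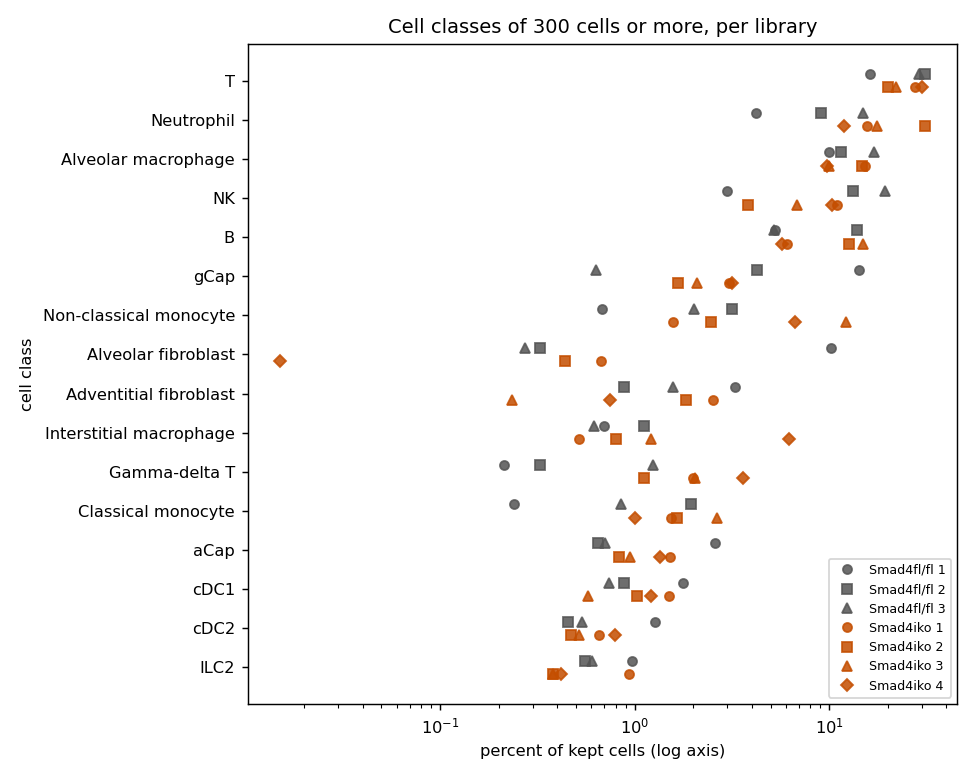
Percent of kept cells (x axis, log scale) in each class with 300 cells or more (y axis); grey symbols are the 3 Smad4fl/fl and orange symbols the 4 Smad4iko libraries, and a share of 0 has no symbol. Neutrophil shares run from 4.19% in Smad4fl/fl 1 to 31.2% in Smad4iko 2, and the alveolar fibroblast share of Smad4fl/fl 1 is 10.2%.

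Gene expression was then compared class by class on UMI counts summed per library. Both capillary classes of Smad4iko lungs had lost most of their Hebp1, which encodes heme-binding protein 1. In Car4-high capillary cells (aCap) Hebp1 fell from 137 ± 65.4 CPM (SD, n = 3) to 7.79 ± 6.73 CPM (SD, n = 4), a log2 change of -4.22 ± 0.46 (SE, edgeR adjusted p = 2.8e-04). In gCap it fell from 83.4 ± 26.0 to 6.16 ± 3.29 CPM, a log2 change of -3.77 ± 0.33 (edgeR adjusted p = 0.00158). All 4 Smad4iko libraries lay below all Smad4fl/fl libraries in both classes. Alveolar macrophages, which expressed Hebp1 most, had 442 ± 14.3 and 459 ± 60.3 CPM (log2 difference -0.02, edgeR adjusted p = 0.978), and no call was made; whether the effect differs between these classes was not tested. Hebp1 (ENSMUSG00000042770) lies on chromosome 6 from 135137522 to 135198022, minus strand. It was the only gene of these 11 classes that the rule fixed for naming genes takes. The other calls of this comparison are named below although they fall outside that rule, and were chosen after their values were seen.

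In aCap, S100a8 and S100a9, which encode the subunits of the neutrophil protein calprotectin, rose. S100a8 went from 9.69 ± 8.86 to 126 ± 92.4 CPM (log2 change 4.11 ± 0.65, edgeR adjusted p = 0.0191) and S100a9 from 22.1 ± 24.4 to 223 ± 171 CPM (3.68 ± 0.64, adjusted p = 0.0431). The aCap level of S100a8 was 0.0808% of that in neutrophils, and S100a8 was higher on average in Smad4iko in all 11 classes, with no overlap between the groups in 9. With Smad4iko 3 and 4 marked by a covariate, S100a8 was also called in B cells and NK cells and S100a9 in B cells (edgeR adjusted p = 0.0148, 0.0166 and 0.0148). Both calls ended without Smad4fl/fl 1, at log2 differences of 3.00 and 2.66 (edgeR adjusted p = 0.185 and 0.205), and with predicted doublets kept, at 0.43 and 0.62 (0.924 and 0.887). S100a9 also did not pass without Smad4fl/fl 2 (0.0971), without Smad4iko 3 (0.0528), with the stricter cell filter (0.0598) or with DESeq2 (0.0975).

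In NK cells, Itga1, the collagen-binding integrin alpha 1 chain known as CD49a on tissue-resident NK cells, rose from 9.69 ± 1.66 CPM (SD, n = 3) to 28.9 ± 6.46 CPM (SD, n = 4). The log2 change was 1.67 ± 0.22 (SE, edgeR adjusted p = 0.0257), with all 4 Smad4iko libraries above all Smad4fl/fl libraries. Its level in NK cells was 0.824% of that in pericytes, under the 10% set beforehand to leave out free RNA. Pianp, a gene best known from the nervous system, fell in NK cells from 24.7 ± 9.05 to 0.0733 ± 0.147 CPM, with 319 UMIs in Smad4fl/fl and 1 in Smad4iko (edgeR adjusted p = 4.9e-04). It also fell in alveolar macrophages, from 43.99 ± 23.3 to 0.287 ± 0.104 CPM (log2 change -7.37 ± 0.56, edgeR adjusted p = 0.00259). In T cells 249 Pianp UMIs stood in Smad4fl/fl and 0 in Smad4iko, and in B cells 85 and 0, without a call (edgeR adjusted p = 0.226 and 0.0745); with the covariate Pianp was called in B cells (log2 change -7.92, adjusted p = 0.0148). Klra3, a receptor of the Ly49 family of NK cells, fell in alveolar macrophages from 21.2 ± 11.9 to 0.173 ± 0.124 CPM (-7.04 ± 0.54, edgeR adjusted p = 0.00259). In NK cells, where Klra3 was highest, it was 375 ± 101 and 234 ± 58.5 CPM and not called (0.617); its level in alveolar macrophages was 2.84% of that in NK cells, also under the 10%. Ly49 genes are near-identical copies, so reads can be split between them and the level of any member is uncertain. The predicted gene Gm44511 fell in NK cells from 18.7 ± 9.87 to 0.0815 ± 0.163 CPM (edgeR adjusted p = 0.00535). The call of Itga1 ended without any 1 of Smad4fl/fl 1, 2 and 3 or of Smad4iko 2 and 4 (edgeR adjusted p = 0.122, 0.299, 0.372, 0.0649 and 0.110), with a sex covariate (0.0838) and with equal cells per library (0.183). That of Gm44511 ended without Smad4iko 4 (0.110).

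Across the 11 classes, edgeR made 9 calls in 90592 tests, 3 higher and 6 lower in Smad4iko, from 7 distinct genes. At an unadjusted p under 0.05 there were 5917. DESeq2 made 177 calls, 115 higher and 62 lower, among them 8 of the 9. No gene passed with edgeR in T cells, B cells, neutrophils, non-classical monocytes, interstitial macrophages, cDC1 or cDC2, the other conventional dendritic cells. At an unadjusted p under 0.05 these held 694, 543, 647, 555, 356, 217 and 274 genes, and DESeq2 called 15, 11, 46, 6, 7, 11 and 1. On simulated counts of T cells in this design, 44.4% of genes changed 2-fold and 88.8% of those changed 4-fold were recovered. In gCap these were 62.2% and 98.0%, and in aCap 68.4% and 100%. False were 2 of 133 calls in T cells, 17 of 176 in gCap and 10 of 177 in aCap. The simulation changed 200 genes at once, and the adjustment is stricter where fewer genes change. These rates therefore do not describe classes with few or no calls, and do not exclude 4-fold changes there. The count was 27 without Smad4iko 1 and 22 without Smad4iko 2. It was 39 with Smad4iko 3 and 4 marked by a covariate and 53 with Smad4iko 1 and 2 alone, and the 9 genes and classes were kept in both. Both rest on Smad4iko 1 and 2 for the genotype effect, so they are not separate checks.

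Of the 9 calls, 6 were of 4 genes on chromosome 6: Pianp (124996694 to 125003096), Gm44511 (128780285 to 128826315), Klra3 (130323289 to 130337574) and Hebp1. The Rosa26 locus, which carries creERT2 in Smad4iko mice and none in the controls, lies on the same chromosome (Gt(ROSA)26Sor, 113067428 to 113077333). With the calls left out, each in its own class only, 69 of 1825 tests within 25 Mb of it had a p under 0.01, or 3.78%, against 1.30% elsewhere. A called gene still counted in its other classes, such as Pianp in B cells (edgeR unadjusted p = 8.6e-06), so this share is not independent of the calls. None of 414 windows of that size that do not overlap it was as high, and the highest reached 2.78% on chromosome 8. The peak was not centred on Rosa26: overlapping windows nearer the end of chromosome 6 reached 4.73%. By class, with the calls of that class left out, the share near Rosa26 was higher than elsewhere in alveolar macrophages, NK cells, T cells and cDC1 (one-sided Fisher's exact test across genes, adjusted p = 2.6e-04, 4.2e-05, 0.00730 and 2.6e-04). Genes are not independent replicates in this test. In the other 7 classes it did not pass, and in neutrophils it was 1.88% near and 2.23% elsewhere. This window test was chosen after the called genes were seen. Without genes within 25 Mb of Rosa26, 1 call remained. Besides the 6, this ended the calls of Itga1 on chromosome 13 and S100a9 on chromosome 3: their log2 changes of 1.67 and 3.68 did not move, and adjustment over the genes left gave an edgeR adjusted p of 0.0754 and 0.0635.

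**Figure D3:**
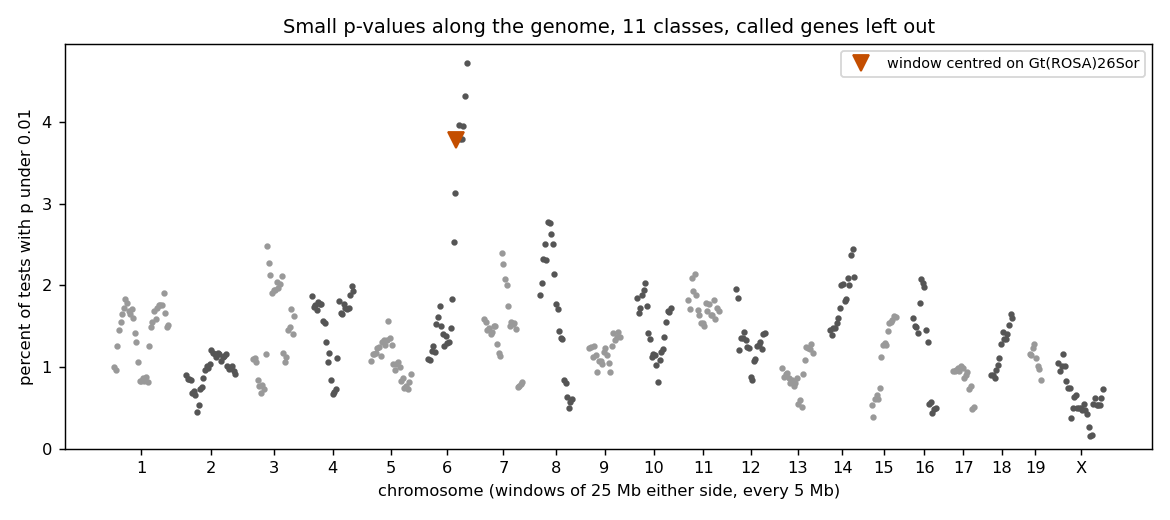
Percent of tests with p under 0.01 (y axis) in windows reaching 25 Mb to either side, centred every 5 Mb along each chromosome (x axis), over the 11 tested classes. Calls are left out in their own class only. The orange triangle is the window centred on Gt(ROSA)26Sor on chromosome 6. That window reaches 3.78%, overlapping windows nearer the end of the chromosome reach 4.73%, and the highest window that does not overlap it reaches 2.78%.

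Of the gene lists fixed beforehand, interferon-stimulated genes, the antiviral program, were higher in Smad4iko T cells for 13 of 15 members (camera adjusted p = 1.1e-06; adjusted p = 0.515 with an estimated correlation). By edgeR 0 members passed over all genes tested and 5 passed when adjusted over the list alone. Of these, Usp18, which restrains interferon signalling, stood at 3.37 ± 0.610 and 6.93 ± 1.10 CPM (log2 difference 1.12 ± 0.23), and Ifit3 at 3.45 ± 0.829 and 7.26 ± 0.932 CPM (1.16 ± 0.25). The T cell chemoattractant Cxcl10 differed by 0.97 ± 0.23 and Rtp4 by 0.72 ± 0.23, and each of these 4 genes lay above all Smad4fl/fl libraries in 4 of 4 Smad4iko libraries. With Smad4iko 3 and 4 marked by a covariate the list had an adjusted p of 1.1e-10 in the same direction (adjusted p = 0.225 with an estimated correlation).

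Immediate early and dissociation genes, which respond to stress and to enzymatic digestion, were lower in Smad4iko aCap for 18 of 18 members (camera adjusted p = 4.5e-08; adjusted p = 0.687 with an estimated correlation). By edgeR 0 passed over all genes and 11 when adjusted over the list alone. The chaperone Hsp90aa1 was 1117 ± 383 against 426 ± 313 CPM (log2 difference -1.41 ± 0.40), Fosb differed by -1.49 ± 0.43, Dnajb1 by -1.12 ± 0.36 and Jund by -0.55 ± 0.20. Part of this list separated Smad4iko 3 and 4 from the other libraries, and with these marked by a covariate its adjusted p in aCap was 0.0127 (adjusted p = 0.748 with an estimated correlation). MHC class II genes, which present antigen to CD4 T cells, were lower in gCap for 7 of 7 members (camera adjusted p = 1.6e-05; adjusted p = 0.687 with an estimated correlation), with 0 members over all genes and 2 when adjusted over the list alone. Cd74 was 549 ± 195 against 225 ± 141 CPM (log2 difference -1.32 ± 0.40), and H2-Aa differed by -0.83 ± 0.28, H2-Eb1 by -0.87 ± 0.33 and H2-Ab1 by -0.52 ± 0.28. This list was also lower in Smad4iko 3 and 4 than in the other libraries (adjusted p = 0.0486; adjusted p = 0.746 with an estimated correlation), and with these marked its adjusted p was 0.0151 (0.713 with an estimated correlation). The gCap level of Cd74 was 0.926% of that in the class with the most.

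In the myeloid classes, inflammatory cytokine and NF-kB genes were lower in Smad4iko non-classical monocytes for 13 of 15 members (camera adjusted p = 1.8e-04; adjusted p = 0.687 with an estimated correlation), and 4 passed when adjusted over the list alone against 0 over all genes. Nfkbiz, a regulator of NF-kB target genes, was 1316 ± 495 against 679 ± 142 CPM (log2 difference -0.97 ± 0.26), Il6 differed by -1.29 ± 0.37, the inflammasome sensor Nlrp3 by -1.09 ± 0.34 and the prostaglandin synthase Ptgs2 by -1.98 ± 0.65. Without Smad4fl/fl 3 the adjusted p of this list was 0.333. TGF-beta-SMAD target genes were lower in Smad4iko alveolar macrophages for 13 of 15 members (camera adjusted p = 0.00149; adjusted p = 0.687 with an estimated correlation), with 1 member when adjusted over the list alone and 0 over all genes. That member was Pmepa1, which TGF-beta induces and which restrains the same pathway, at 119 ± 22.7 against 60.2 ± 21.3 CPM (log2 difference -1.06 ± 0.24, 4 of 4 Smad4iko libraries below all Smad4fl/fl libraries; DESeq2 adjusted p = 0.0124). Tgfbi was 338 ± 64.7 against 250 ± 25.2 CPM, also with 4 of 4 below, and Timp3 differed by -2.43 ± 0.91 and Ldlrad4 by -0.31 ± 0.17. This list was also lower in Smad4iko 3 and 4 than in the other libraries (adjusted p = 0.00625; adjusted p = 0.477 with an estimated correlation), and with these marked it did not pass (0.587). Cytotoxic lymphocyte genes were lower in Smad4iko neutrophils for 6 of 6 members (camera adjusted p = 1.9e-05; adjusted p = 0.687 with an estimated correlation), 5 of them when adjusted over the list alone and 0 over all genes. Neutrophils held Gzmb at 0.141%, Prf1 at 0.212%, Gzma at 0.217% and Nkg7 at 0.309% of the level in the class with the most, far under the 10% set for free RNA. With predicted doublets kept the adjusted p of this list was 0.0642. The log2 differences of these genes were -1.96 ± 0.53, -2.42 ± 0.72, -1.95 ± 0.67 and -1.67 ± 0.61.

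Over all lists and classes, camera with a preset correlation called 47 of 203 tests, 19 higher and 28 lower in Smad4iko. With an estimated correlation it called 0, with 10 at an unadjusted p under 0.05. With the preset correlation, other groupings of the 7 libraries into 3 and 4 called 17 to 59 lists.

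The last comparison asked whether the genotype effect differed between gCap, T cells and neutrophils, the largest tested classes of their compartments. limma called 0 genes for gCap against neutrophils, 0 for gCap against T cells and 0 for T cells against neutrophils, Smad4 included. At an unadjusted p under 0.05 there were 450 of 6506, 462 of 8778 and 594 of 7086 genes. The test recovered 0% of genes simulated to differ 2-fold between T cells and neutrophils and 5% of those differing 4-fold, so it would find few differences of that size between these classes. The pairs with gCap were not simulated.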

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

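Of the tests in this part, the 2 on S100a8 in neutrophil RNA and in neutrophils or doublets among T cells were written before their result was seen; all others, including the counts of other splits of the libraries, were chosen after the result was seen.

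Libraries far from the others of their group were looked for in 73 values of the 4 Smad4iko libraries, and 11 lay past Dixon's limit of 0.829; chance marks about 1 in 20 groups. Smad4 in non-classical monocytes was 38.5 CPM in Smad4iko 3 against 68.8 to 74.6 in the others. Pianp in alveolar macrophages was 0.131 CPM in Smad4iko 1 against 0.326 to 0.349, a difference among near-empty values. Single UMIs set apart Pianp in NK cells of Smad4iko 1 (0.293 CPM), Gm44511 in NK cells of Smad4iko 4 (0.326 CPM) and C1s2 in adventitial fibroblasts of Smad4iko 2 (0.796 CPM), each against 0 in the others. Klrk1, the NKG2D receptor, was 5.93 CPM in plasmacytoid dendritic cells of Smad4iko 3 against 14.7 to 15.9. Interstitial macrophages were 6.21% of cells in Smad4iko 4 against 0.517% to 1.22%. Type 2 innate lymphoid cells were 0.941% in Smad4iko 1 against 0.379% to 0.421%, and basophils 0.255% in Smad4iko 4 against 0.106% to 0.125%. Smad4iko 3 kept 8142 cells against 6378 to 6656 and had 3.22% predicted doublets against 2.25% to 2.30%.

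The first pattern weighed is that Smad4iko 3 and 4 stood apart from the other 5 libraries in T, B and NK cells, neutrophils and alveolar macrophages. Sex is argued against, since the female Smad4fl/fl 3 had 1.80% of its T cells in the cluster that holds 77.5% and 69.2% of those of Smad4iko 3 and 4. A library batch stays possible. The difference of these libraries from the rest correlated across genes between classes with a median of 0.228 over the pairs of classes. Pairs ran from 0.0148 (NK cells and aCap) to 0.673 (T and NK cells), so the median mixes related and unrelated classes. Between lymphocytes and capillary classes all pairs were 0.0877 or lower, while T cells and neutrophils reached 0.350. A shift common to every class of a library is therefore not shown. A state that these mice shared predicts a correlation between classes as well, and the labels give no batch. A stronger loss of Smad4 stays open, because the median log2 difference of Smad4 in Smad4iko 3 and 4 from 1 and 2 was -0.19 over 11 classes and of either sign between them.

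The second pattern is the run of called genes on chromosome 6, where 10 of the 20 calls over 16 classes lay 11.5 to 22.1 Mb from Rosa26 and 9 of the 10 were lower in Smad4iko. DNA around the Rosa26 creERT2 allele, inherited with it from another strain, is a candidate explanation. With calls left out in their own class only, 3.78% of tests within 25 Mb of Rosa26 had a p under 0.01. At most 2.78% did in 414 windows that do not overlap it, though the excess passed in 4 of the 11 classes taken singly. Called genes still counted in classes without a call, so this is partly the same evidence. The excess was not centred on Rosa26, as overlapping windows nearer the end of the chromosome reached 4.73%, and sequence differences between strains were not analysed here. The loss of 1 altered copy in 2 is argued against, because 9 of the 10 calls lay below -1 on the log2 scale by more than 2 SE. Loss of Smad4 itself stays open for these genes, since it goes with creERT2 in all 4 Smad4iko mice and Smad4 remained at 59.2% of the control level in T cells.

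The third pattern is that S100a8 and S100a9 were higher on average in all 11 classes of Smad4iko lungs, although aCap alone passed the test without a covariate (with Smad4iko 3 and 4 marked, S100a8 also passed in B and NK cells and S100a9 in B cells; edgeR adjusted p = 0.0148, 0.0166 and 0.0148). Free RNA from neutrophils may account for most of it in T, B and NK cells and alveolar macrophages: divided by the S100a8 level of the whole library, a median share of 0.154 of the log2 difference was kept over these 4 classes, and in T cells it went from 3.55 to 0.53. Neutrophils or doublets counted in the class are argued against as the main source in 5 classes. Of the Smad4iko S100a8 UMIs, 8.98% in aCap, 13.2% in T cells, 14.1% in NK cells, 17.9% in B cells and 36.2% in alveolar macrophages lay in cells with 5 or more. Without such cells the log2 ratio of the group means kept a share of 0.966 in aCap and at least 0.877 in B cells, NK cells and alveolar macrophages. In non-classical monocytes, cDC1, cDC2 and gCap the measures part, so this source stays open there. Such cells held 81.1%, 85.4%, 93.6% and 55.8% of the Smad4iko UMIs, while a share of at least 0.597 of the log2 ratio was kept. In interstitial macrophages a share of 0.40 was kept, so such cells may hold most of the difference there; neutrophils themselves were not part of these tests. A rise in each class from the loss of Smad4 stays open. Beyond the rise of the whole library little was left in T, B and NK cells and alveolar macrophages: the highest share kept was 0.257, and alveolar macrophages turned to -1.17. In NK cells a log2 difference of 1.05 stayed, with an exact permutation p of 0.0286. A rise in every class, neutrophils included, would cancel in this division. In neutrophils S100a8 was at 11880 to 37520 CPM in Smad4fl/fl and 52940 to 86060 CPM in Smad4iko, so the division cannot tell such a rise from free RNA.

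Other splits of the 7 libraries into 3 and 4 were tested for each model, 35 splits in all. For the total of 9 calls over the 11 classes, 8 splits gave as many, so chance cannot be excluded, and the highest other gave 639. That split joins Smad4fl/fl 2 with Smad4iko 3 and 4 and points to a structure of the samples: 475 of its calls were in interstitial macrophages, and these 3 libraries had 62 of 79, 71 of 99 and 372 of 413 of these cells in 1 cluster led by Lyz1 and Fn1. For alveolar macrophages taken alone chance can be excluded, with a real count of 2 and a highest other of 1, but 1 of 35 splits is the smallest share possible and this was 1 of 11 classes tested, so chance is not excluded over the classes together. It cannot be excluded for NK cells (2 of 35; real 3, highest other 6), aCap (4 of 35; 3 and 13) or gCap (6 of 35; 1 and 72). With a real count of 0 all 35 splits were as large in B cells (highest other 19), interstitial macrophages (475), neutrophils (42), non-classical monocytes (19), T cells (18), cDC1 (35) and cDC2 (78). The same holds for cell class shares (0 and 1) and differences between classes (0 and 1). Chance cannot be excluded for the 47 lists (5 of 35, highest other 59) or for the 6 calls within 25 Mb of Rosa26 (2 of 35, highest other 17, in the split with 639 calls). For the 1 class in which Smad4 passed over the 11 classes, 2 of 35 splits were as large (highest other 3). The other of these set Smad4iko 2, 3 and 4 apart from the other 4 libraries. It holds much of the genotype contrast, so this count cannot decide on chance. The share of the calls that lay near Rosa26 was 66.7% against a highest other of 11.1%, but the 16 splits that made calls are too few for a share under 0.05. Chance cannot be excluded for the ratio of the percent of tests with p under 0.01 near Rosa26 to that elsewhere, calls of the split left out in their own class (3 of 35, real 2.91 and highest other 4.51). Both higher splits set 3 Smad4iko libraries apart from the other 4.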

How the results depend on the processing

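The covariate for Smad4iko 3 and 4 (for lists also with an estimated correlation), Smad4iko 1 and 2 alone, and genes near Rosa26 left out were chosen after seeing the data; the other alternatives were planned. Of 1358 alternative values, 1196 kept their direction and their side of the threshold (or a count within 1.5 times), 83 passed or rose where the reported value did not, 58 fell short and 21 turned their direction. Unless a cause is named, the cause was not tested.

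The total of 9 calls was 177 with DESeq2, 15 with equal cells per library, 39 with the covariate, 53 with Smad4iko 1 and 2 only (22 of them on chromosome 7) and 760 without a low-count filter. It was 5 with free RNA left out and 1 with genes near Rosa26 left out, where fewer genes were tested; of the 8 calls lost there, Itga1 and S100a9 lie on other chromosomes and ended by the new adjustment alone (adjusted p = 0.0754 and 0.0635). Leaving out each library in turn gave 7 (without Smad4fl/fl 1) to 27 (without Smad4iko 1) calls. By DESeq2 the counts were 48 in alveolar macrophages, 11 in B cells, 7 in interstitial macrophages, 19 in NK cells, 46 in neutrophils, 6 in non-classical monocytes, 15 in T cells, 7 in aCap, 11 in cDC1, 1 in cDC2 and 6 in gCap. Without the low-count filter they were 9, 135, 4, 123, 219, 36, 2, 129, 22, 27 and 54 in the same order. With the covariate there were 10 in alveolar macrophages, 12 in B cells, 6 in NK cells and 7 in neutrophils. With Smad4iko 1 and 2 only there were 20 in alveolar macrophages, 12 in B cells, 8 in NK cells, 2 in neutrophils, 5 in T cells and 3 in gCap. Genes near Rosa26 left out gave 0 in alveolar macrophages, NK cells and gCap and 1 in aCap. With free RNA left out there was 1 in alveolar macrophages and 1 in aCap. Equal cells per library gave 1 in non-classical monocytes and 7 in aCap, and the sex covariate 4 in alveolar macrophages and 2 in cDC1. When each library was left out, alveolar macrophages had 2 to 5 calls (most without Smad4fl/fl 3), B cells 0 to 1 (Smad4iko 3), NK cells 1 to 5 (fewest without Smad4iko 4, most without Smad4iko 1), and neutrophils 0 to 1 (Smad4iko 1 or 2). Non-classical monocytes had 0 to 2 (most without Smad4iko 2), aCap 1 to 17 (fewest without Smad4fl/fl 1, most without Smad4iko 1), cDC1 0 to 2 (Smad4iko 2) and gCap 1 to 3 (Smad4iko 2).

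Of the list calls, 0 were left with an estimated correlation, with or without the covariate, and 87 were made without a low-count filter, against 47. Smad4 in T cells passed over all genes with DESeq2 (log2 -0.66). Smad4 in neutrophils turned from -0.03 to 0.00395 without a low-count filter, 0.0816 with the covariate, 0.0602 with Smad4iko 1 and 2 only and 0.000545 with equal cells per library. Leaving out each library gave -0.28 to 0.15 in neutrophils, -0.60 to 0.0178 in interstitial macrophages and -0.46 to 0.00832 in non-classical monocytes. The share of alveolar macrophages turned from -0.04 to 0.10 with the stricter cell filter and 0.23 with the covariate and with Smad4iko 1 and 2 only, and leaving out each library gave -0.20 to 0.22. It gave -1.89 to 0.0353 for gCap and -0.27 to 0.15 for T cells. These signs turned around differences that no test called.

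The replicate block, with libraries of the same number in both groups as a pair, made 60 calls in total: 5 in alveolar macrophages, 8 in B cells, 1 in interstitial macrophages, 12 in NK cells, 10 in neutrophils, 6 in non-classical monocytes, 6 in aCap, 6 in cDC1 and 6 in gCap, and the share of alveolar macrophages was 0.075. The call of Itga1 in NK cells ended under it (edgeR adjusted p = 0.0530). The numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.14 to 0.40 for number 1, -0.23 to -0.06 for number 2 and 0.04 to 0.16 for number 3. Depth sets the counting error of Smad4, which in Smad4fl/fl rests on 160 UMIs in non-classical monocytes and 79 in interstitial macrophages, against 4497 in T cells. Whether depth limits the calls was not tested. Recovery of simulated 2-fold changes was 68.4% in aCap and 44.4% in T cells, among 5505 and 10971 genes left by the low-count filter. These sets of genes differ, so the rates do not compare depth.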

Other observations

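The tests in this part were chosen after the result was seen, except the gene list tests between the genotypes without a covariate and the sex covariate, which were planned.

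In 5 classes with at least 15 cells in every library, edgeR made 11 further calls. Classical monocytes of Smad4iko lungs had less Cd83, a marker of activated antigen-presenting cells, at 160 ± 20.9 against 609 ± 62.8 CPM (log2 change -1.95 ± 0.18, edgeR adjusted p = 0.00192). Malt1, a protease of NF-kB signalling, fell by 1.52 on the log2 scale (adjusted p = 0.0330), Jak2 by 1.53 (0.0470) and the TGF-beta-induced Pmepa1 by 1.92 (0.0470). Gamma-delta T cells had more Ly6a, the surface protein known as Sca-1, at 103 ± 21.9 against 8.30 ± 1.47 CPM (log2 change 3.65 ± 0.38, adjusted p = 0.00166). The Smad4fl/fl level in these gamma-delta T cells rests on 8 UMIs (1, 1 and 6), against 430 in Smad4iko, so its SD is uncertain. In these cells Pxdc1 fell by 1.82 and the AP-1 subunit Fosl2 by 1.04 (adjusted p = 0.0363 each). Their Smad4 was 38.5 ± 5.33 against 89.2 ± 14.8 CPM (log2 difference -1.05 ± 0.24, edgeR adjusted p = 0.152 over all genes). Plasmacytoid dendritic cells had more of the activation marker Cd69 (log2 change 1.58 ± 0.26, adjusted p = 0.0427) and less Klrk1 (-2.80 ± 0.43, adjusted p = 0.0418). In adventitial fibroblasts C1rb, a rodent copy of complement C1r, had 568 UMIs in Smad4fl/fl and 0 in Smad4iko, at least 155-fold lower against a floor of 3 counts over the group (adjusted p = 0.0157). C1s2, a copy of C1s, fell too (log2 change -7.05 ± 0.91, adjusted p = 0.0362), and reads of both can be shared with their paralogs. Ly6a in gamma-delta T cells stood at 1.61% of its level in aCap, Pmepa1 at 3.31% of that in Schwann cells, Pxdc1 at 8.33% of that in AT1 cells of the alveolar epithelium and Klrk1 at 9.21% of that in NK cells, each under the 10% set for free RNA. In each of these calls all 4 Smad4iko libraries lay on 1 side of all 3 Smad4fl/fl libraries. C1rb (124570294 to 124581171), C1s2 (124624625 to 124636085), Cd69 (129267325 to 129275436) and Klrk1 (129610323 to 129623864) lie on chromosome 6, within 25 Mb of Rosa26. They belong to the run of called genes on that chromosome weighed above. With Smad4iko 3 and 4 marked by a covariate, C1s2 (edgeR adjusted p = 0.226), Klrk1 (0.139), Jak2 (0.0725), Pmepa1 (0.0572), Cd69 (0.0553) and Malt1 (0.0517) no longer passed. Their log2 changes were then -6.84, -2.61, -1.51, -1.93, 1.58 and -1.44, close to those without the covariate, with larger SE (1.06 against 0.91 for C1s2 and 0.23 against 0.20 for Malt1). With sex as a covariate Cd69 (0.0960), C1s2 (0.0741), Klrk1 (0.0650), Pmepa1 and Jak2 (0.05996 each) did not pass. Other calls were gained: gamma-delta T cells had 16 with sex and 16 with Smad4iko 3 and 4 marked, against 3. With these libraries marked, edgeR also called S100a8 and Gadd45b in classical monocytes (adjusted p = 0.0477 each) and Pianp in adventitial fibroblasts (0.0113). In plasmacytoid dendritic cells it called S100a8, S100a9 (0.00323 each) and Ccr2 (0.0085). S100a8 stood there at 0.521% of its neutrophil level. Smad4iko 2, with 30 of these cells, held S100a8 at 2275 CPM and S100a9 at 3388 CPM. The other Smad4iko libraries held 36.7 to 74.1 and 50.2 to 89.0 CPM, and Smad4fl/fl 0 to 12.4 and 9.50 to 29.9 CPM. The size of both changes therefore rests mostly on 1 library. Type 2 innate lymphoid cells had 0 calls with edgeR, with 62 at an unadjusted p under 0.05, and DESeq2 was not run in these 5 classes.

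Several lists moved in more classes than those described above, each by camera with the preset correlation and lost with an estimated one (adjusted p = 0.687 each). Interferon-stimulated genes were also higher in Smad4iko B cells (adjusted p = 8.2e-04), neutrophils (0.00316) and interstitial macrophages (0.0301). MHC class II genes were also lower in non-classical monocytes (0.00845) and alveolar macrophages (0.0117). Inflammatory cytokine and NF-kB genes were also lower in interstitial macrophages (1.8e-04), alveolar macrophages (3.8e-04), cDC1 (0.00101) and neutrophils (0.00403). This list was lower in Smad4iko 3 and 4 than in the other libraries in alveolar macrophages (8.6e-16; 0.477 with an estimated correlation) and interstitial macrophages (0.00766; 0.746). With these libraries marked it passed in cDC1 (0.0296) and not in interstitial macrophages (0.134), alveolar macrophages (0.581) or neutrophils (0.152), and the MHC class II list no longer passed in non-classical monocytes (0.326). Interstitial macrophages also lay in different clusters by library, with 372 of 413 cells of Smad4iko 4 and 1 of 43 of Smad4fl/fl 3 in 1 of them. BMP-SMAD target genes, the other arm of SMAD4 signalling, were called in none of the 11 classes, with adjusted p = 0.973 in gCap and 0.675 in aCap. TGF-beta-SMAD target genes were called in 1 class, alveolar macrophages. With Smad4iko 3 and 4 marked by a covariate that call was lost (adjusted p = 0.587), and the list was lower in NK cells (8.9e-05) and T cells (0.0188). BMP-SMAD target genes were then lower in T cells (0.0220) and NK cells (0.0228). With an estimated correlation beside the covariate none of these 4 passed (adjusted p = 0.599 each). Smad7, a member of both lists, was called lower in B cells with the covariate (log2 change -0.92, edgeR adjusted p = 0.034). Without it the edgeR adjusted p was 0.513. The groups did not overlap in B cells (330 to 411 CPM in Smad4fl/fl, 176 to 227 in Smad4iko). Nor did they in T cells, NK cells, cDC2 and non-classical monocytes, where edgeR did not call it. They overlapped in aCap, gCap, cDC1, neutrophils, alveolar macrophages and interstitial macrophages.

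Immediate early and dissociation genes followed the difference of Smad4iko 3 and 4 from the other libraries. By camera they were lower in these libraries in gCap (adjusted p = 2.7e-32; 0.477 with an estimated correlation) and aCap (3.1e-29; 0.477), and higher in NK cells (6.1e-25; 0.119), B cells (1.6e-16; 0.204) and T cells (2.3e-16; 0.119). Between the genotypes the list was higher in B cells (adjusted p = 0.00104; 0.687 with an estimated correlation) and lower with those libraries marked (0.0416; 0.599). In gCap it was lower (0.0131; 0.780) and then higher (0.00111; 0.748), so these calls too were lost with an estimated correlation. The beta-globin transcript Hbb-bs was at 484 and 280 CPM in T cells of Smad4iko 3 and 4, at 20.4 and 12.3 in Smad4iko 1 and 2, and at 0.135, 5.73 and 3.36 in Smad4fl/fl 1 to 3. In 8 of 11 classes both libraries had more Hbb-bs than any other.

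A cluster of genes on chromosome 7 set Smad4iko 1 and 2 apart from all other libraries. Trim12a (104299894 to 104315466) was at 48.0 and 50.4 CPM in their T cells, 0, 0.176 and 0.462 CPM in Smad4fl/fl 1 to 3 and 0 in Smad4iko 3 and 4. Its neighbour Trim30d (104470014 to 104507849) was at 40.3 and 48.2 CPM in their neutrophils and at 0 in Smad4fl/fl 1 and 3 and Smad4iko 3 and 4, with 0.714 CPM in Smad4fl/fl 2. With Smad4iko 1 and 2 alone against the controls, 22 of the 53 calls of edgeR were on chromosome 7. Trim12a was called in 6 classes, with a log2 change in B cells of 7.002 ± 0.42 (edgeR adjusted p = 5.0e-05). These Trim genes are a family of close copies, so the level of each is uncertain. No explanation of this difference was tested.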
